A study of Homo sapiens with 17 samples.

How the data were processed

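The series holds 17 Illumina HumanHT-12 bead arrays, 1 per sample, of human coronary artery endothelial cells on nonrestricted collagen regions (3 arrays) or on Disk (3), Crossbow (3), H (3), L (3) and Y (2) micropatterns. Per the labels, the authors purified total RNA, checked it by spectrophotometer and capillary electrophoresis, and amplified and labelled it with biotin in a kit for polyadenylated RNA. The authors deposited a non-normalized table whose signal columns hold intensity on a linear scale, with the background still in it (lowest signal on an array 61.8 to 72.0 units). Beside each signal, the deposited table gives a detection p-value of the probe against the negative control beads of its own array. The authors also deposited a processed matrix of intensity, which was found to be each array's signal times 1 factor (0.736 to 1.19) that gives every array a mean of 119.2, on a linear scale without background subtraction or centring. Its medians ranged from 66.0 to 99.2. Scanner software, bead filters, slides and batches are not given in the sources used here.

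Of 47323 probes, the platform table gave 30113 exactly 1 gene symbol and 8 several, and 17202 had no symbol. Of the named probes, 30074 took their current symbol through the gene identifier in a RefSeq table of the human assembly GRCh38.p14. No coordinates are given, since neither the array's build nor probe positions are in the sources used here, and probes that may read several related genes could not be screened by sequence.

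Signals were corrected for background with normexp on the detection p-values and quantile normalized on the log2 scale (neqc; limma 3.58.1 in R 4.3.3), with an offset of 16. The 19047 probes with a detection p-value under 0.05 on at least 2 arrays were tested; 13660 of them were named, for 11006 genes. Measurement precision rests on signal over background: between 21.9% and 28.2% of probes were detected per array, and the median SD between arrays of a group, over 2444 probes with a mean above 7 log2, was 0.051 to 0.085 log2 in the shapes and 0.14 in the nonrestricted group (0.051 without replicate 2). A fold change against a group with no detected array is given as a bound, against that group's detection floor, as "at least", and no fold is given where both means lie below the floor. For genes detected on part of a group, differences with values raised to each array's floor were added after the data were seen.

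limma fitted 1 model with 6 group means (residual degrees of freedom 11, prior 6.69). Contrasts were the mean of the 5 shape means against nonrestricted, each shape against nonrestricted, a moderated F test over the differences among the 5 shapes, and each shape against the mean of the other 4 (adjusted together over the 5 contrasts). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons, gene lists, rule for named genes and alternatives were chosen before the data were examined, unless stated otherwise. Gene lists (39) were tested with camera (preset correlation 0.01) on the brightest tested probe of each gene, adjusted over the lists, with an estimated correlation beside it. One list is not reported here. The others were lists for SRF and MRTF, YAP and TAZ, integrins, tubulins, the nuclear envelope, histones, DNA replication, mitosis, p53, FOXO, autophagy, ATF4, ER chaperones, heat shock, hypoxia, cholesterol, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, immediate early genes, NF-kB, interferon, flow, endothelial identity, junctions, Notch, tip cells, TGF-beta, matrix, matrix remodelling, coagulation, apoptosis, and smooth muscle, mesenchymal, fibroblast, leukocyte, epithelial and lymphatic markers.

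Named genes have a probe with exactly 1 symbol, not a provisional one. In patterned against nonrestricted growth they are the 10 largest rises and 10 largest falls past the threshold with all 5 shape means on the same side of the control. For each shape they are the 3 largest rises and 3 largest falls. Among the shapes they are the 10 smallest F test p-values, and for each shape against the others the 2 largest rises and 2 largest falls. For each list they are the members with the smallest p-values, 4 for lists past the threshold and 2 for the others, and given as values where they did not pass. Where another tested probe of a named gene had the other sign, or only 1 of them was called, over the mean of the shapes, that is stated. Genes of the sex chromosome Y and XIST were not named.

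The steps were tested once each on simulated data of the same size with known changes. Noise was drawn independently for each probe and array, and 200 probes were changed for the probe tests. Without correlation between genes, few false calls, above all of lists, say little about correlated genes. Of changes of 0.25 log2, limma recovered 5.97% in patterned against nonrestricted growth and 0% on Disk, and the F test 0%. In patterned against nonrestricted growth, limma recovered 73.1% of changes of 0.5 log2 and 98.5% of 1 log2, with 6 false calls, and for Disk 32.8% and 89.4%, with 8 false calls. The F test recovered 23.9% and 89.4%, with 7 false calls, the contrasts of a shape with the others 45.5% over all sizes, with 6 false calls, and camera all of 3 changed lists, with 0 false calls.

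Alternatives were other background corrections and scalings (normexp with an offset of 50, no correction with a floor of 16, median centring, and the authors' scaled values), no filter, a stricter filter (detection p under 0.01 in every array of a group), a replicate block, array weights, only the groups compared, each array left out in turn, and for lists the estimated correlation, fry and the probe with the lowest p. Replicate numbers did not pair the arrays: after removing group means, the correlation between arrays of the same number had a median of -0.0015 (40 pairs) and between those of different numbers -0.0012 (80 pairs). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.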

Results

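The study measured whole-genome mRNA levels in human coronary artery endothelial cells (HCAEC), primary cells of the inner wall of the heart's arteries, on Illumina bead arrays. Cells had grown for 48 h without serum on collagen I micropatterns of 1 area, 1600 square micrometres, that force a spread cell into a set outline, or on nonrestricted collagen I regions. The 17 arrays covered nonrestricted growth (3 arrays), Disk (3), Crossbow (3), H (3), L (3) and Y (2). The mean signal per array lay between 99.8 and 161.9 units, and 10345 to 13362 of 47323 probes were detected above background. Disk arrays detected the most probes (13083 to 13362), H arrays 12234 to 12487, Y arrays 12590 to 13262, L arrays 12120 to 12473, Crossbow arrays 10595 to 11861 and nonrestricted arrays 10345 to 11813. Within groups, arrays correlated at 0.954 to 0.993 across tested probes, which are not independent replicates. The lowest value involved nonrestricted replicate 2, on which 19 bright probes read at background. The number of arrays limits the precision, and every p-value here measures only the spread between arrays, which may be technical. The labels state 18 independent biological replicates per shape without saying how these map onto arrays.

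Patterned against nonrestricted growth asks what confinement to a small adhesive area does to the transcriptome of serum-starved endothelial cells. Probes for short nuclear RNAs gave the largest rises. RNVU1-7, a variant copy of the U1 RNA of the spliceosome (probe ILMN_3244646), rose from 4.49 ± 0.12 (SD, n = 3) on nonrestricted arrays to a mean of 8.69 over the shapes, a log2 fold change of 4.20 (SE 0.073; adjusted p = 2.9e-17), and lay above all control arrays on 14 of 14 patterned arrays. It was detected on 1 of 3 control arrays and its control mean lay below the detection floor, so the size is read against background. With values under the floor raised to it, the difference was 4.04, against 4.05 for RNVU1-18, so the 2 are not ranked. RNVU1-18 (4.12) and RNU1-3 (3.20), further U1 copies, also rose. SNORD3A, a copy of the U3 RNA that processes ribosomal RNA precursors, rose by 2.99 log2. SNORD3C, another U3 copy, was undetected on every control array and was at least 7.81-fold higher on patterned arrays, and RN7SK, the 7SK RNA that restrains transcription elongation, was at least 6.75-fold higher. A probe cannot separate near-identical U1 or U3 copies.

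Genes of cell division gave the largest falls. SPC24, a subunit of the kinetochore (probe ILMN_2181432), fell by 3.16 log2 (SE 0.096; adjusted p = 5.3e-14), from 8.83 ± 0.11 (SD, n = 3) to a mean of 5.67. BIRC5, the survivin of the chromosomal passenger complex (probe ILMN_2349459), fell by 2.94 log2 (SE 0.081; adjusted p = 1.6e-14) and was detected on 4 of 14 patterned arrays against 3 of 3 control arrays, so that its size too is read against background (-2.84 with values raised to the floor). PRC1 and NUSAP1, which organise the spindle, had log2 fold changes of -2.37 and -2.23, CCNF, cyclin F, of -2.14, and UHRF1, which maintains DNA methylation at replication, of -2.22. EDN1, the vasoconstrictor endothelin-1 (probe ILMN_1682775), fell by 2.15 log2 (SE 0.071; adjusted p = 1.6e-13) from 9.79 ± 0.011 (SD, n = 3). TOB1, an antiproliferative regulator, fell by 2.21 log2, the transporter gene SLC35F2 fell by 2.06 log2, and the ubiquitin ligase gene RNF144B fell by 2.06 log2. All of these falls were seen on 14 of 14 patterned arrays, and none changed direction under another scaling of the arrays. Some rest on part of the patterned arrays: NUSAP1 was detected on 12 of 14, TOB1 on 10 and UHRF1 on 9.

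4 of the 10 largest rises need a limit each. TUBA3FP, a tubulin pseudogene whose probe may read other tubulins, had a log2 fold change of 2.86 (SE 0.99; adjusted p = 0.036), which was 0.20 (adjusted p = 0.067) without nonrestricted replicate 2. Its call also ended without Y replicate 1 (adjusted p = 0.057) or Y replicate 2 (adjusted p = 0.055). RPL38, of the large ribosomal subunit, had 2.56 with all arrays and 0.53 (adjusted p = 7.2e-05) without nonrestricted replicate 2, and another RPL38 probe gave 0.17 (adjusted p = 0.15). SNRPD2, of the core of spliceosomal particles, had 2.56 with all arrays and 0.46 (adjusted p = 0.00014) without that array. Without a filter on dim probes these calls ended as well (adjusted p = 0.14 for TUBA3FP, 0.073 for RPL38 and 0.085 for SNRPD2). POTEF, which carries an actin domain close in sequence to beta-actin, rose by 2.42 log2 and by 2.19 without that array. It was detected on 2 of 3 control arrays, and its rise was 2.26 log2 with values raised to the floor.

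**Figure D1:**
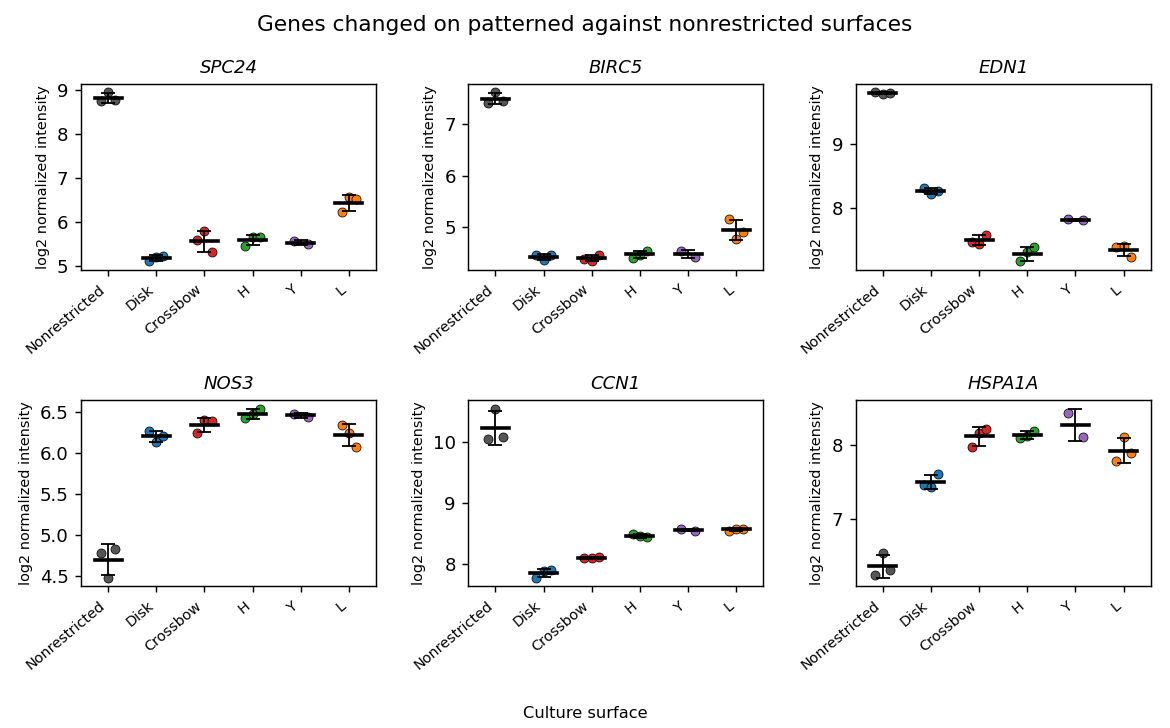
Log2 normalized intensity (vertical axes) of 6 genes on each array (points), by culture surface, with group means (thick bars) and SD (error bars); n = 3 arrays per group and 2 for Y. SPC24, BIRC5, EDN1 and CCN1 lay lower, and NOS3 and HSPA1A higher, on 14 of 14 patterned arrays than on the control arrays, and none of these changed direction under another scaling.

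Mitosis genes fell together: of 25 measured of 30 listed, 20 fell, 0 rose and 5 did not pass (21 and 0 adjusted over the list alone). NUSAP1 and BIRC5 led the list, CDC20, an activator of the anaphase-promoting complex, fell by 1.77 log2, and AURKB, the Aurora B kinase, was detected on 3 of 3 control arrays but on 1 of 14 patterned arrays, with a patterned mean below the detection floor (-1.57 log2 with values under the floor raised to it). The list's mean was -0.87 (camera adjusted p = 2.3e-12; adjusted p = 0.00016 with an estimated correlation), and it stayed below 0 under every scaling tried. Of 18 measured DNA replication genes of 23, 9 fell and 0 rose (10 and 0 adjusted over the list alone). RRM1, the large subunit of ribonucleotide reductase, fell by 1.47 log2, TK1, a thymidine kinase, fell by 1.53 log2, and MCM4, of the replicative helicase, fell by 1.60 log2 (TK1 detected on 11 of 14 patterned arrays, MCM4 on 10). That list's camera adjusted p was 4.3e-06 (adjusted p = 0.0022 with an estimated correlation), but its mean of -0.61 came to -0.047 under median centring, where 4 members fell and 3 rose and the list, tested against other genes, still passed camera (adjusted p = 0.00016).

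Ribosomal protein genes rose: of 40 measured of 45, 26 rose, 3 fell and 11 did not pass (28 and 3 adjusted over the list alone; camera adjusted p = 3e-05; adjusted p = 0.0022 with an estimated correlation). RPS13 (0.77), RPL23 (1.13) and RPL14 (0.81) rose, and RPL22 fell by 0.65 log2, with the opposite sign under median centring (0.21). Heat shock proteins rose too, with 11 of 18 measured of 19 higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 0.00035; adjusted p = 0.0092 with an estimated correlation). HSPA1A and HSPA1B, inducible HSP70 genes whose probes may read both, rose by 1.63 and 1.08 log2, DNAJA1, an HSP40 cochaperone, rose by 1.04 and BAG3, a cochaperone of selective autophagy, by 1.12. Both lists rose under every scaling tried.

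YAP and TAZ targets, which read out mechanical tension on the cell, were lower in 10 and higher in 3 of 18 measured of 22 (10 and 3 adjusted over the list alone; camera adjusted p = 0.0062; adjusted p = 0.031 with an estimated correlation), but the list's mean of -0.37 turned to 0.096 under median centring, which raised probes above 7 log2 by a median of 0.92, and its camera call ended there (adjusted p = 0.17) and with the authors' scaled values (mean -0.21; adjusted p = 0.33). AXL, a receptor tyrosine kinase, fell by 1.99 log2 (SE 0.074) and CCN1, a matricellular protein, by 1.93 (SE 0.086), each under every scaling. ASAP1, a regulator of focal adhesions, fell by 0.57 log2 but was higher under median centring (0.28) and with the authors' scaled values (0.0027), and DOCK5 fell by 0.80 log2, a call that ended under median centring (adjusted p = 0.30). Tubulins and microtubule proteins were lower in 9 and higher in 1 of 13 measured of 15 (9 and 2 adjusted over the list alone; camera adjusted p = 0.021, but adjusted p = 0.12 with an estimated correlation). The list's mean of -0.24 turned to 0.45 under median centring and 0.097 with the authors' scaled values. Its members called higher numbered 2 without nonrestricted replicate 3 or Crossbow replicate 2. TUBB4B fell by 1.13 log2 (adjusted p = 0.16 under median centring), TUBB3 rose by 0.68, and TUBA1A (-0.44) and TUBB6 (-0.52) fell but were higher under both of those scalings.

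The other lists did not pass the camera test, so their counts describe members and no direction of the list. Those that passed under an alternative are named after them. Of 17 measured SRF and MRTF targets, which respond to actin polymerisation, 3 rose and 5 fell (camera adjusted p = 0.24, 3 and 6 adjusted over the list alone), and 12 rose and 1 fell under median centring. CNN2, an actin-binding calponin, fell by 1.63 log2, and an ACTB probe rose by 2.36 log2 while another ACTB probe fell by 1.83. Of 29 integrin and focal adhesion genes, 8 rose and 5 fell (0.83, 8 and 5 over the list alone), among them LPP (-0.67; 0.21 under median centring) and TES (0.73, or 0.56 with values raised to the floor, detected on 1 of 3 control arrays; adjusted p = 0.42 with the authors' scaled values). Of 14 nuclear envelope genes, 5 rose and 4 fell (0.98, 6 and 4 over the list alone), and 3 rose and 2 fell without nonrestricted replicate 2. BANF1, which binds chromatin to the envelope, fell by 0.73 log2 and TOR1AIP1 by 0.69, and both were higher under median centring (0.16 and 0.11). Of 7 histone genes, 3 rose and 1 fell (0.70, 3 and 1 over the list alone): H2AC18 was at least 1.78-fold higher and H4C3 fell by 1.99 log2.

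Vascular genes split. NOS3, the endothelial nitric oxide synthase, rose by 1.64 log2 (SE 0.083; adjusted p = 6.7e-11) from 4.70 ± 0.19 (SD, n = 3), and rose in each shape, by 1.50 to 1.78 log2. It was detected on 2 of 3 control arrays, with a control mean near the floor, so its size is read against background. With values raised to the floor, its rise was 1.57 log2. KLF2, the flow-induced transcription factor, rose by 0.65. Of 7 flow-induced genes, 4 rose and 1 fell (camera adjusted p = 0.24, 4 and 1 adjusted over the list alone), 3 and 0 without nonrestricted replicate 3. Of 14 coagulation and vasoactive genes, 8 rose and 1 fell (0.061, 8 and 1 over the list alone), 7 and 2 without nonrestricted replicate 2, with NOS3 up and EDN1 down. Without nonrestricted replicate 3 the camera adjusted p of this list was 0.038, but without nonrestricted replicate 2 it was 0.25. Of 20 endothelial identity genes, 7 rose and 4 fell (0.70, 7 and 4 over the list alone), 7 and 2 without nonrestricted replicate 2. CD34, a sialomucin of endothelial and progenitor cells, fell by 1.64 log2. It was detected on 11 of 14 patterned arrays (-1.61 with values raised to the floor). Of 14 Notch and arterial genes, 7 rose and 2 fell (0.059, 8 and 2 over the list alone), and the camera adjusted p was 0.044 without nonrestricted replicate 2. HEY1, a Notch target, rose by 1.18 and JAG2, a Notch ligand, by 0.96. Of 12 tip cell and angiogenesis genes, 3 rose and 3 fell (0.79, 3 and 3 over the list alone): ANGPT2, the TIE2 ligand angiopoietin-2, rose by 0.73 and APLN, apelin, fell by 1.40 log2 (detected on 7 of 14 patterned arrays). Of 18 cell junction genes, 4 rose and 3 fell (0.98, 4 and 3 over the list alone), 7 and 3 without nonrestricted replicate 2. CDH2, N-cadherin, fell by 1.72 log2 and PKP4 by 0.91 (adjusted p = 0.82 under median centring).

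Matrix and signalling genes also moved both ways. Of 24 extracellular matrix genes, 7 rose and 5 fell (camera adjusted p = 0.98, 9 and 6 adjusted over the list alone), 4 and 4 without nonrestricted replicate 2. THBS1, the antiangiogenic thrombospondin-1, fell by 1.57 log2 and LAMA5, a laminin chain, rose by 0.86. Of 17 matrix remodelling genes, 6 rose and 3 fell (0.97, 6 and 3 over the list alone): MMP1, a collagenase, rose by 1.47 and its inhibitor TIMP1 by 1.26. Of 11 TGF-beta and BMP targets, 4 rose and 2 fell (0.70, 4 and 2 over the list alone), with the inhibitors of differentiation ID1 (1.69) and ID3 (0.83) higher; 1 fell without nonrestricted replicate 1 or 3. Of 16 immediate early genes, 4 rose and 3 fell (0.98, 4 and 3 over the list alone), with IER3 at 0.53 and EGR1 at -0.44, which was 0.33 under median centring. Of 13 NF-kB and leukocyte adhesion genes, 2 rose and 1 fell (0.97, 2 and 1 over the list alone), 1 and 1 without nonrestricted replicate 2 and 2 and 2 without nonrestricted replicate 3: PTGS2, cyclooxygenase-2, rose by 1.25 (1.18 with values raised to the floor, as it was detected on 1 of 3 control arrays) and NFKBIA fell by 0.71 log2 (0.12 under median centring). Of 17 interferon response genes, 5 rose and 2 fell (0.78, 5 and 2 over the list alone), 5 and 1 without nonrestricted replicate 1, with ISG15 at 0.93 and IFI6 at -0.93, whose call ended under median centring (adjusted p = 0.99).

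Stress and metabolic lists were mixed. Of 17 ATF4 targets, 9 rose and 2 fell (camera adjusted p = 0.057, 10 and 2 adjusted over the list alone). ATF4 rose by 0.73 and PSAT1, of serine synthesis, fell by 0.92 log2 (adjusted p = 0.96 under median centring). Without nonrestricted replicate 3 that list's camera adjusted p was 0.046, and 0.05 without Y replicate 1, where it passed. Of 16 ER chaperones, 7 rose and 4 fell (0.70, 9 and 5 over the list alone), and the falls of EDEM1 (-1.08) and PDIA6 (-0.94) were not called under median centring (adjusted p = 0.40 and 0.82). Of 17 autophagy and lysosome genes, 6 rose and 2 fell (0.17, 6 and 2 over the list alone), 6 and 1 without nonrestricted replicate 2, with ULK1, a kinase that starts autophagy, at 1.07 and the lysosomal channel gene MCOLN1 at 0.85. Of 28 hypoxia and glycolysis genes, 6 rose and 11 fell (0.12, 6 and 11 over the list alone), 5 and 7 without nonrestricted replicate 1 and 16 and 1 under median centring. PKM, a pyruvate kinase, fell by 1.38 log2 and LDHA by 0.69 (0.21 under median centring). Of 28 oxidative phosphorylation genes, 10 rose and 2 fell (0.14, 10 and 2 over the list alone), led by COX5B (0.58) and COX7A2 (0.60); 0 fell without nonrestricted replicate 3, and 1 without nonrestricted replicate 1 or 2 or Y replicate 1. Of 18 cholesterol synthesis genes, 2 rose and 5 fell (0.20, 2 and 5 over the list alone), with EBP at -1.36 and HMGCS1 at -0.85, which was 0.060 under median centring. Of 15 ribosome biogenesis genes, 3 rose and 4 fell (0.47, 3 and 4 over the list alone), with NOP56 at -1.44 and NCL at -0.64, which was 0.23 under median centring; 0 rose without nonrestricted replicate 3, and 1 without nonrestricted replicate 1, any Disk array, H replicate 2, either Y array or L replicate 2.

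Growth-arrest and death regulators followed no single direction. Of 20 p53 targets, 3 rose and 5 fell (camera adjusted p = 0.19, 4 and 5 adjusted over the list alone), but 0 rose and 3 fell without nonrestricted replicate 2, and 1 rose without Disk replicate 2 or 3, H replicate 2 or 3, or Y replicate 2. BAX, which permeabilises mitochondria, fell by 0.98 log2 (adjusted p = 0.55 under median centring), and TP53INP1 by 0.42, with the opposite sign under median centring (0.40) and with the authors' scaled values (0.034). Of 13 FOXO targets, 4 rose and 1 fell (0.59, 4 and 1 over the list alone), 2 and 1 without nonrestricted replicate 1: BCL6, a transcriptional repressor, rose by 0.77, and DEPP1 fell by 0.40 log2 but was higher under median centring (0.46) and with the authors' scaled values (0.15). Of 14 apoptosis regulators, 2 rose and 5 fell (0.13, 2 and 5 over the list alone), 1 and 5 without nonrestricted replicate 1 or 2, led by BCL2L1, which encodes BCL-XL, at -1.29.

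Lists of markers of other cell types held few measured members, and none passed in the analysis reported. Of 5 measured smooth muscle markers of 10, 1 rose and 1 fell (camera adjusted p = 0.83, 1 and 1 adjusted over the list alone): SMTN fell by 0.52 log2 (0.093 under median centring), and TAGLN rose by 0.31 (adjusted p = 0.010), a call that ended without nonrestricted replicate 2 (0.21; adjusted p = 0.093), where 0 rose and 2 fell. Of 4 mesenchymal transition genes, 0 rose and 2 fell (0.057, 0 and 2 over the list alone), CDH2 and VIM (-0.73; 0.22 under median centring), and without nonrestricted replicate 3 the camera adjusted p was 0.032, and it was 0.05 and passed without nonrestricted replicate 2 or Y replicate 1. Of 5 fibroblast markers, 1 rose and 1 fell (0.61, 1 and 1 over the list alone), COL1A2 (adjusted p = 0.026, but 0.064 to 0.075 without any 1 of the control arrays, and lower with the authors' scaled values, at -0.12) and COL1A1 (-0.70; 0.19 under median centring). COL1A2 was detected on 0 of 3 control and 8 of 14 patterned arrays, with both means below the detection floor, so no fold is given. Of 4 leukocyte markers, LYZ fell by 0.52 log2 (adjusted p = 0.83 under median centring) and CD3D, detected on 0 of 3 control and 2 of 14 patterned arrays, did not pass (adjusted p = 0.17; list 0.78, 0 and 1 over the list alone). Of 3 epithelial markers, CLDN7 was at least 1.28-fold higher, with -0.023 in the authors' scaled values, and EPCAM, detected on 0 of 3 control and 2 of 14 patterned arrays, did not pass (adjusted p = 0.59; list 0.59, 1 and 0 over the list alone). Of 2 lymphatic markers, RELN had 0.28 (adjusted p = 0.045), a call that ended without any of 11 arrays in turn (adjusted p = 0.051 to 0.24), and CCL21, detected on 1 of 3 control and 1 of 14 patterned arrays, did not pass (adjusted p = 0.19; list 0.98, 1 and 0 over the list alone).

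Some of these lists passed camera under an alternative. ATF4 targets passed as higher without background correction (adjusted p = 0.046), under median centring (0.0033), with the authors' scaled values (0.0012), without a filter (0.0036) and with the probe of lowest p (0.032). Under median centring, the authors' scaled values and no filter, oxidative phosphorylation (9.4e-06, 4.1e-10 and 0.0089), autophagy (0.00019, 7.4e-07 and 0.018) and Notch genes (0.018, 0.019 and 0.017) passed as higher. Under the first 2 of these, integrins (0.021 and 0.0018), ER chaperones (0.021 and 0.0012) and endothelial identity (0.014 and 0.00014) passed as higher, and cell junctions, whose mean was -0.028 in the analysis reported and 0.25 there, under the second (0.0066). Coagulation genes passed as higher without a filter (0.018) and with the probe of lowest p (0.03), and hypoxia targets as lower with that probe (0.032), against a mean above 0 under median centring (0.48) and with the authors' scaled values (0.12). SRF and MRTF targets passed as lower with that probe (0.00045) but as higher with the authors' scaled values (0.019). Mesenchymal transition genes passed as lower with normexp and an offset (0.035) and without background correction (0.039).

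The median and mean of members differed in sign for cholesterol synthesis (0.016 and -0.17), ribosome biogenesis (0.047 and -0.13), NF-kB (-0.067 and 0.058), cell junctions (0.040 and -0.028), TGF-beta (-0.036 and 0.21), matrix remodelling (-0.014 and 0.065) and smooth muscle (0.026 and -0.021). The camera direction was down against a positive mean for NF-kB and the nuclear envelope (mean 0.028).

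In all, 5618 of 19047 tested probes (29.5%) passed an adjusted p of 0.05, 3147 higher and 2471 lower, and of these 158 were higher and 309 lower by at least 2-fold. They represent 3903 genes of 11006, 2302 higher and 1601 lower by their brightest probe. Without nonrestricted replicate 2, 5156 probes passed. Among 407 genes with several called probes, 70 had probes called in opposite directions (17.2%). For some named genes another tested probe was called the other way over the mean of the shapes (TAGLN -0.47, YY1 0.39, and an ACTB probe) or had the other sign without a call: ATF4 (-0.059), BAX (0.043), HEY1 (-0.26), IFI6 (0.11), NBPF10 (0.0098), NOP56 (0.056), SMTN (0.018), a further TAGLN probe (-0.0059), TCEAL9 (0.071), TES (-0.24), TOR1AIP1 (0.15) and VIM (1.83; adjusted p = 0.11), whose probe read at background on nonrestricted replicate 2 (10.74 and 10.80 on the other control arrays against 4.20), so that its sign rests on that array. Other probes of AFMID, BCL2L1, CD34, COL6A3, LPP, NOP56, RPL38, SMTN, TP53INP1 and WSB1 had the same sign without a call. The share called higher depended on the scaling: quantile normalization gives every array the same distribution, and 56.0% of its calls were higher, whereas median centring, which leaves the brighter signals of patterned arrays in place, called 6707 probes higher and 311 lower, and the authors' scaled values called 3419 higher and 12599 lower. The median log2 fold change of all tested probes was 0.024, 0.10 and -0.18 under these scalings, and that of the 2444 probes above 7 log2 was 0.097, 0.92 and 0.50, so every fold change is relative to the rest of its array.

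**Figure D2:**
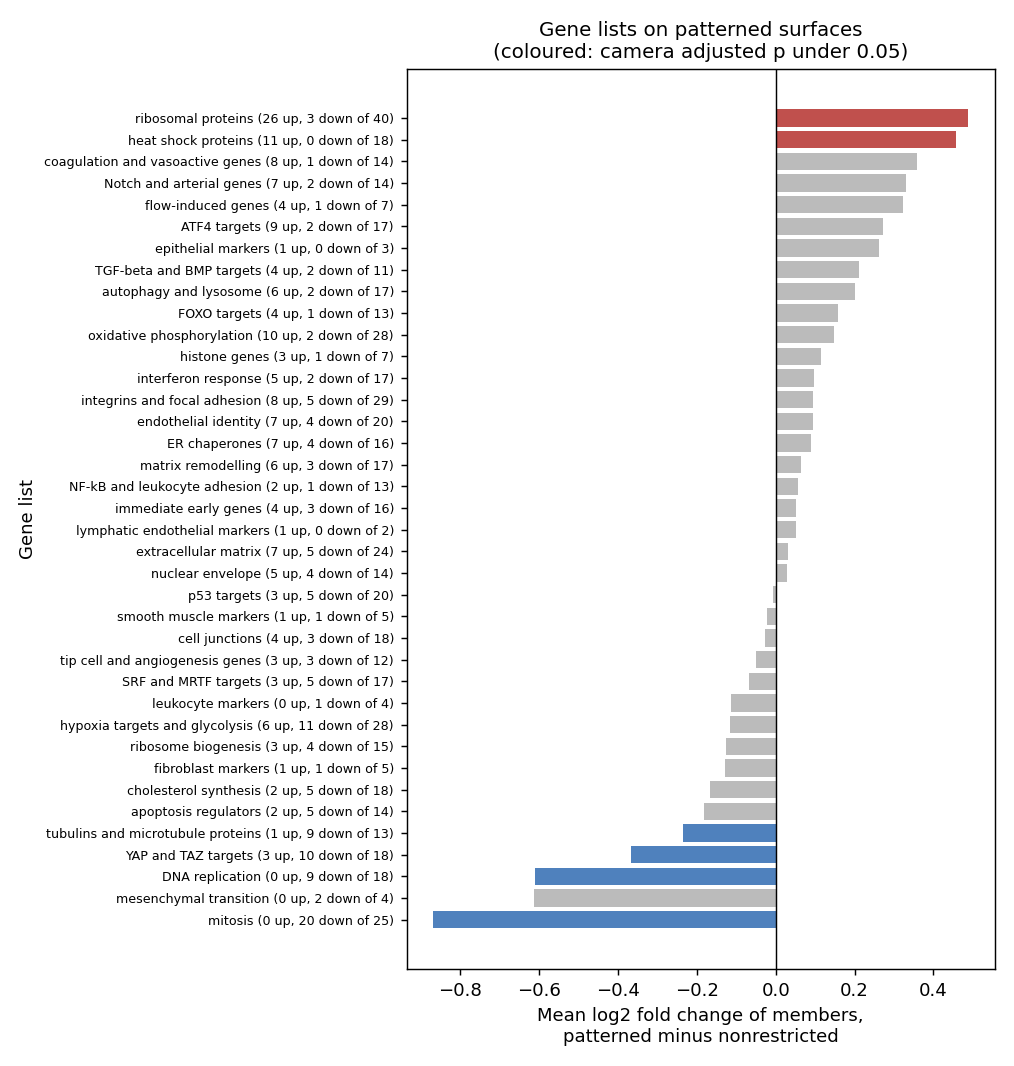
Mean log2 fold change, patterned minus nonrestricted, of the measured members of 38 gene lists (bars), with members called up or down; coloured bars passed the camera test. Mitosis lay lowest at -0.87 and kept its sign under every scaling, whereas the YAP and TAZ list (median centring) and the tubulin list (median centring and the authors' scaled values) changed sign. The tubulin bar is coloured, but that list did not pass camera with an estimated correlation (adjusted p = 0.12).

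Each shape against nonrestricted growth asks whether every outline gives these changes. Among named genes, RNVU1-7 and RNVU1-18 gave the largest rises in every shape, and RNVU1-7, near background in controls, had 3.71 on H to 4.22 on L with values raised to the floor. On Disk, a filled circle, RNVU1-7 rose by 4.18 log2 (SE 0.094), RNVU1-18 by 4.14, and RN7SK was at least 9.8-fold higher. AXL fell by 3.67 log2 (SE 0.095; adjusted p = 7.5e-15), SPC24 fell by 3.65 log2, and BIRC5, undetected on Disk arrays, was at least 7.75-fold lower. On Crossbow, an outline with a curved front, RNVU1-7 rose by 4.22 and RNVU1-18 by 4.14, RN7SK was at least 10.9-fold higher, SPC24 fell by 3.26 log2, and BIRC5 was at least 7.21-fold lower. KCNAB1, a regulatory subunit of potassium channels, fell by 2.66 log2 (SE 0.11). On H, RNVU1-7 rose by 3.87 and RNVU1-18 by 3.82, SNORD3C was at least 6.66-fold higher, SPC24 fell by 3.23 log2 and BIRC5 was at least 7.54-fold lower. H4C3, a histone H4 gene, fell by 3.19 log2 (SE 0.11).

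On Y, with 2 arrays, RNVU1-7 rose by 4.33 log2 (SE 0.10), RNVU1-18 by 4.25 and RNU1-3 by 3.35. SPC24 fell by 3.30 log2, BIRC5, detected on 1 of 2 arrays, fell by 3.00 log2 (2.94 with values raised to the floor), and COL1A1, the alpha-1 chain of type I collagen, fell by 3.03 log2 (SE 0.15; adjusted p = 1.7e-10). On L, RNVU1-7 rose by 4.38 log2 (SE 0.094) and RNVU1-18 by 4.26, and SNORD3C was at least 9.01-fold higher. NBPF10, of a repeated gene family whose copies a probe may not separate, fell by 2.81 log2 (SE 0.091), BIRC5 fell by 2.54 log2, and CDK11A, a kinase of transcription and splicing with a near-identical neighbour, was undetected on L arrays and at least 5.38-fold lower.

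By count, Disk changed 5207 probes (3113 higher, 2094 lower), Crossbow 4593 (2372 higher, 2221 lower), H 4249 (2439 higher, 1810 lower), Y 3782 (2199 higher, 1583 lower) and L 4371 (2454 higher, 1917 lower). Y changed 2290 probes without Y replicate 1 and 2450 without Y replicate 2. Fitted with only the groups compared, Crossbow changed 2552 probes, Y 1563 and L 2539. Under median centring the counts were 7985 for Disk, 1624 for Crossbow and 8103 for Y, and with the authors' scaled values they ranged from 2819 for Crossbow to 16331 for Disk. In all 5 shapes, 981 probes were higher and 839 lower. Independent calls would give 0.738 and 0.194, but calls that share 1 control are not independent. In 20 simulations of unchanged probes sharing 1 control, 0 and 0 were called in all shapes. Those simulations called a mean of only 0.2 probes in at least 1 shape, against 7971 in the data. They therefore cannot show how much overlap a shared control gives. The 3 control arrays cannot be split into separate controls of at least 2, so part of the overlap may come from the shared control.

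**Figure D3:**
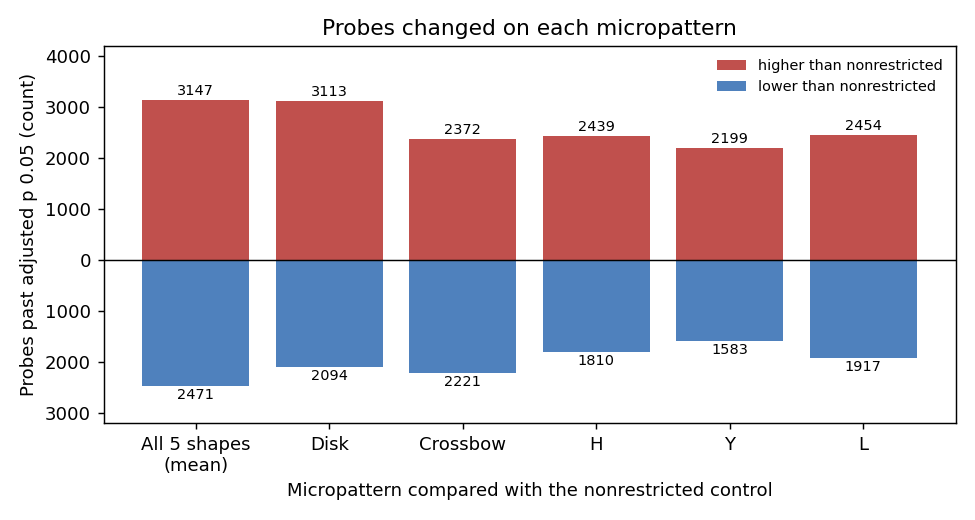
Probes past an adjusted p of 0.05 (vertical axis, count) higher (red, upward) or lower (blue, downward) than on nonrestricted regions, for the mean of the 5 shapes and for each shape. Disk has the most calls of the single shapes here, 3113 higher and 2094 lower, but Y has more under median centring (8103 against 7985), and the higher share depends on the scaling, with 6707 higher and 311 lower for the mean of the shapes under median centring.

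Differences among the 5 shapes ask whether the outline matters when the adhesive area is the same. AXL (probe ILMN_1701877) had the smallest F test p-value (adjusted p = 9e-12), a rank by p-value and not by size. From 12.3 ± 0.17 (SD, n = 3) on nonrestricted arrays, it stood at 8.63 ± 0.060 on Disk, 9.79 ± 0.038 on Crossbow and 10.58 ± 0.023 on H (SD, n = 3 each). On Y it stood at 10.9 ± 0.0096 (SD, n = 2) and on L at 11.61 ± 0.063 (SD, n = 3). The COL1A1 means lay further apart. COL1A1 (probe ILMN_1701308; adjusted p = 1e-11) rose on Crossbow by 1.42 log2 and had log2 fold changes of -1.42 on Disk, -0.74 on H and -3.03 on Y, with 0.26 on L (adjusted p = 0.19). Under median centring the Crossbow rise (1.61) and the Y fall (-1.61) remained called, but Disk (-0.18; adjusted p = 0.54) and H (0.16; adjusted p = 0.63) did not. NBPF9 and NBPF10 differed at 3.7e-11 and 2.7e-11, with the lowest level of both on L (log2 fold changes of -2.22 and -2.81). WSB1, a substrate adaptor of a ubiquitin ligase (adjusted p = 5.1e-10), ranged from 0.22 on Disk (adjusted p = 0.10) to -2.01 on L. H4C3 (4.8e-09) fell on each shape, with log2 fold changes from -0.98 on Disk to -3.19 on H, and CDK11A (7.4e-09) from -0.92 on Disk to -2.49 on L.

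TCEAL9, a transcription elongation factor-like gene (adjusted p = 2.1e-08), had log2 fold changes of 0.58 on Disk and -1.10 on L, and YY1, a zinc finger transcription factor (3e-08), of 0.68 on Disk and -1.24 on L; over the mean of the shapes another YY1 probe had 0.39. Under median centring the L values were -0.33 for TCEAL9 (adjusted p = 0.083) and -0.42 for YY1 (adjusted p = 0.038), and over the mean of the shapes both genes were higher under that scaling (0.38 and 0.35), not lower (-0.42 and -0.49). IL1RL1, the interleukin-33 receptor (3e-08), was lower on Disk (-1.17) and Crossbow (-0.60) and higher on Y (0.60) and L (0.62), so that its mean over the shapes (-0.10; adjusted p = 0.43; 0.0067 without nonrestricted replicate 2) did not pass, whereas another IL1RL1 probe fell by 0.61 over that mean (adjusted p = 0.00016). Under median centring the Disk and Crossbow values of the first probe were -0.097 and -0.28 (adjusted p = 0.65 and 0.30). By the F test 4087 of 19047 probes (21.5%) differed among the shapes, in 2859 genes.

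**Figure D4:**
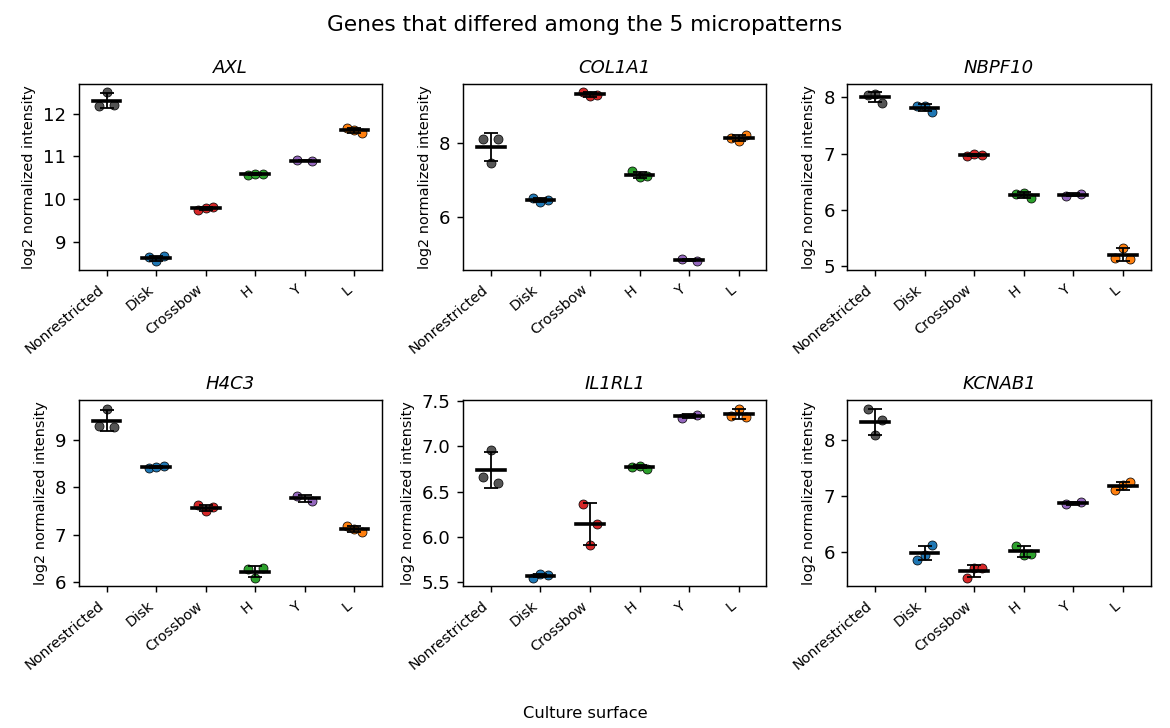
Log2 normalized intensity (vertical axes) of 6 genes on each array (points), by culture surface, with group means (thick bars) and SD (error bars); n = 3 arrays per group and 2 for Y. AXL stepped from 8.63 on Disk to 11.61 on L, and COL1A1 was highest on Crossbow (9.30) and lowest on Y (4.85).

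Each shape against the mean of the other 4 asks which outline a difference belongs to. Disk had higher NBPF9 (2.03, SE 0.082) and NBPF10 (1.64), and lower AXL (-2.09, SE 0.076) and AFMID, an enzyme of tryptophan breakdown (-1.34). Crossbow had higher COL1A1 (2.65, SE 0.11; adjusted p = 8.2e-11) and a higher ACTB probe (1.32), and lower ST13, an HSP70 cochaperone (-1.33), and PDS5B, a cohesin regulator (-1.25). H had a higher ACTB probe (0.72) and MORF4L1, a chromatin reader (0.70), lower H4C3 (-1.50, SE 0.086), and COL6A3, a collagen VI chain undetected on H arrays, was at least 1.48-fold lower. Y had higher IL1RL1 (0.88) and AXL (0.75), lower COL1A1 (-2.91, SE 0.13; adjusted p = 2e-10), and COL6A3 was at least 1.51-fold lower. L had higher AXL (1.63, SE 0.076) and COL1A1 (1.20), and lower NBPF10 (-1.64) and NBPF9 (-1.54). None of these differences changed direction or lost its call under the alternatives in which it was fitted again. Single genes were not fitted again with array weights or with only the groups compared.

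Over the 5 shapes this gave 6999 calls, 3432 higher and 3567 lower. Crossbow had 2842 (1177 higher, 1665 lower), Disk 1662 (918 higher, 744 lower), L 1504 (770 higher, 734 lower), H 645 (349 higher, 296 lower) and Y, with 2 arrays, 346 (218 higher, 128 lower). At least 2-fold differences numbered 39 higher and 21 lower for Disk, 13 and 12 for Crossbow, 9 and 20 for L, and 0 and 1 for H and for Y. Under median centring there were 15588 calls and with the authors' scaled values 30303.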

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

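The tests on other groupings of the arrays were fixed before the results were seen; all other tests of explanations here were chosen after. In 100 splits of the 17 arrays into 3 and 14, the real split alone reached 5618 probes (highest other 1748). Chance in how the arrays fell into groups can be excluded for that count. For lists, 2 splits, the real one included, put at least 6 past the threshold. That share of 2 in 100 lies under 0.05. The other split put more lists past it (7) than the real one, so the count of lists alone does not exclude chance. In 100 regroupings of the 14 patterned arrays, 1, the real one, reached 4087 probes among the shapes (highest other 24). For calls of a shape against the others, 1, the real one, reached 6999 (highest other 39). As for the probes of patterned growth, chance in how the arrays fell into groups can be excluded for both. Chance differences between cultures are not excluded by any of these counts, since the labels do not say whether the arrays of a group came from separate cultures. For a single shape against nonrestricted growth, 10 splits are too few for a share under 0.05: the real split was 1 of 10 with as many calls for Disk (5207, highest other 0), Crossbow (4593, highest other 18), H (4249, highest other 1) and L (4371, highest other 1).

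The response differed between shapes by the F test for 4087 probes. For 196 of them, 1 or more shapes were higher and 1 or more others lower than nonrestricted growth. Such opposite calls against the control depend on the scaling: 173 of the 196 kept them with normexp and an offset, 170 without background correction, 51 with the authors' scaled values and 6 under median centring. COL1A1 differed at an adjusted p of 1e-11, higher on Crossbow (1.42) and lower on Disk (-1.42), H (-0.74) and Y (-3.03). NBPF9 differed at 3.7e-11, higher on Disk (0.63) and lower on Crossbow (-0.63), H (-1.24), Y (-1.49) and L (-2.22). TCEAL9 differed at 2.1e-08, higher on Disk (0.58) and lower on H (-0.91), Y (-0.51) and L (-1.10). YY1 differed at 3e-08, higher on Disk (0.68) and lower on Crossbow (-0.54), H (-0.97), Y (-0.37) and L (-1.24). The falls on Y reversed with a call under median centring, for YY1 (0.763, adjusted p = 9e-04) and TCEAL9 (0.601, adjusted p = 0.0034). With the authors' scaled values YY1 was also called higher on Y (0.175, adjusted p = 0.027). The YY1 falls on Crossbow and H were not called under median centring (adjusted p = 0.41 and 0.76). The Disk rises of both genes stayed called under both scalings. IL1RL1 differed at 3e-08, lower on Disk (-1.17) and Crossbow (-0.60) and higher on Y (0.60) and L (0.62). ST13 differed at 5e-05, lower on Crossbow (-0.81) and higher on Disk (0.61) and L (0.72).

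On patterned arrays 14 probes for ribosomal, U1, U3, U6 and 7SK RNA were higher. These were the ribosomal RNA and snRNA probes called higher in this same fit, with the U3 copies, so the set was chosen for its rise. The RNU11 probes, and all but 6 of 70 snoRNA probes, were not called higher. The Crossbow arrays, which detected about as many probes as the controls, had a median log2 fold change of 2.44 for these probes. On Disk it was 2.34, so the rise was no smaller on Crossbow. These values cannot decide on brighter arrays, since quantile normalization removes brightness by construction and the probes were chosen over all shapes, Crossbow included. Crossbow arrays also had higher mean signals (113.6 to 116.4) than the controls (99.79 to 113.2). For these probes the tables argue against quantile normalization, since the unnormalized signals differed by a median of 1.8 log2 against 0.78 for all bright probes. The bright probes were not chosen for a rise, which limits that comparison. More amplification of RNA without a poly(A) tail cannot be told apart from a change in the cells: histone mRNAs, which lack the tail, had a median of 0.133, but fewer dividing cells would also lower them. A change of these RNAs with confinement stays open as well, untested.

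On the array of nonrestricted replicate 2, 19 probes that were bright on the other control arrays read at background, among them FTL, the ferritin light chain (12.62 and 12.65 against 4.12), RPL8 (11.29 and 11.26 against 4.16) and YWHAZ (10.80 and 10.77 against 4.10), genes chosen after their values were seen. Loss of the transcripts from that RNA is argued against by 11 other probes of 7 of these genes, whose median difference was 0.12 log2, with 0 of them over 1 log2 below. The median difference over 1344 bright probes was -0.014 log2. It cannot decide on a weak signal of the whole array, since quantile normalization gives every array the same distribution. Before normalization this array had the lowest mean signal of all arrays (99.79) and the fewest detected probes (10345), so that explanation stays open. A fault of single beads or of a region of the array may remain, was not tested, and needs bead-level files. No biological explanation was tested, since the design gives none within a group.

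Mitosis and DNA replication genes were lower on patterned arrays. Scaling as the whole cause is argued against for mitosis, whose mean log2 fold change nearest to 0 under the other scalings was -0.313 (SE over members 0.083), but not for DNA replication, where it was -0.047 (SE 0.093) under median centring, which keeps that explanation open for its fold change, although the list still passed camera against other genes (adjusted p = 0.00016). Both SEs are over the genes of a list, which they take as independent, and leave out the spread between arrays. Nonrestricted replicate 2 as the cause is argued against, since without it the larger camera adjusted p of both lists was 1.2e-05. Separate processing of the control arrays cannot be told apart from confinement, since 0 arrays had a named slide. Less division of confined cells is a candidate explanation that these arrays could not test against separate processing.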

How the results depend on the processing

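Every alternative here was planned, except where stated. Of 159 named-gene results, normexp with an offset, no background correction and the replicate block each kept the direction and the call of all 159. The stricter filter kept the 155 it still tested, and no filter kept 154 and ended 5 calls. Median centring kept 125, ended 13 calls and reversed 21. The authors' scaled values kept 136, ended 10, made 1 call and reversed 12. Leaving out 1 array kept 2288 of 2307 values, ended 18 calls and reversed 1. The 21 reversals under median centring were all of values below 0 by less than 1 log2, so the direction of such small falls against nonrestricted growth depends on the scaling: patterned arrays were brighter, which quantile normalization removes by construction and median centring, whose median lies among undetected probes, leaves in place. Signal over background limits dim genes, since 21.9% to 28.2% of probes were detected per array.

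Under median centring, calls numbered 7985 for Disk, 1624 for Crossbow, 8103 for Y, 7816 among the shapes and 15588 for a shape against the others, and 11 lists passed. The tubulin list (0.45) and these genes were higher instead of lower over the mean of the shapes: COL1A1 0.188, WSB1 0.0139, TCEAL9 0.38, YY1 0.352, IL1RL1 0.607, ASAP1 0.284, LPP 0.208, TUBA1A 0.341, TUBB6 0.371, BANF1 0.156, TOR1AIP1 0.111, TP53INP1 0.397, DEPP1 0.455, LDHA 0.21, HMGCS1 0.0596, RPL22 0.209, NCL 0.234, EGR1 0.333, NFKBIA 0.118, SMTN 0.0925 and VIM 0.215. With the authors' scaled values, calls numbered 16018 for patterned growth, 16331 for Disk, 2819 for Crossbow, 13570 for H, 15919 for Y, 12300 for L, 15192 among the shapes and 30303 for a shape against the others, and 14 lists passed. With them the tubulin list (0.097), TCEAL9 (0.0329), YY1 (0.0303), IL1RL1 (0.187), ASAP1 (0.00266), TUBA1A (0.0842), TUBB6 (0.0536), TP53INP1 (0.034) and DEPP1 (0.15) were higher instead of lower, and COL1A2 (-0.12), CD3D (-0.177), CLDN7 (-0.023) and EPCAM (-0.22) lower instead of higher. The cause of each single reversal was not tested.

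Fitted with only the groups compared, which leaves fewer arrays for the spread, Crossbow gave 2552 calls, Y 1563 and L 2539; for patterned growth this is the fit reported. Without a filter on dim probes 12 lists passed, with fry 30 and with the probe of lowest p per gene 10; the cause was not tested, except that fry does not compare a list with other genes. With the replicate block, calls numbered 5568 for patterned growth, 5141 for Disk, 4527 for Crossbow, 4201 for H, 3555 for Y, 4290 for L, 3829 among the shapes and 6375 for a shape against the others, and 6 lists passed. With array weights, calls numbered 4535 for patterned growth, 5341 for Disk, 3709 for Crossbow, 4099 for H, 3540 for Y and 3661 for L. They numbered 5619 among the shapes and 10108 for a shape against the others, and 6 lists passed. Nonrestricted replicate 2 had the lowest weight (0.224). A slide block was not run, since the headers name no slide.

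Leaving out 1 array at a time, with the normalization kept, gave 5156 to 5689 calls for patterned growth, 4255 to 5139 for Disk, 4159 to 4603 for Crossbow, 3485 to 4261 for H, 2290 to 3955 for Y, 3640 to 4341 for L, 3260 to 3831 among the shapes and 5317 to 6164 for a shape against the others (patterned arrays left out), and 6 to 9 lists. The lower Y counts come from fewer samples: 2290 without Y replicate 1 and 2450 without Y replicate 2, where the lone Y array is assumed to vary like the other groups. The 9 lists came without nonrestricted replicate 3, which added ATF4 targets, coagulation and vasoactive genes, and mesenchymal transition. Without nonrestricted replicate 2, IL1RL1 was 0.00667 instead of below 0 (-0.176 to 0.00667 over the arrays left out), and, as the estimated spread fell, 5231 probes differed among the shapes and 9713 calls fell to a shape against the others.

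For the lists by shape and for the probes called on opposite sides of the control in different shapes, the planned background corrections and scalings were applied after the data were seen. Of 52 list results by shape past the threshold, all those of the lists reported, normexp with an offset kept 50 and no background correction 49. Under median centring 30 kept their sign and call, 9 calls ended and 13 had a mean of the other sign. These were DNA replication on Disk (0.0557) and Y (0.149), YAP and TAZ targets on Disk (0.112), H (0.116) and Disk against the others (0.0191), and cholesterol synthesis on Disk (0.323) and Disk against the others (0.0631). The others were tubulins on Disk (0.629), Y (0.779) and Disk against the others (0.225), hypoxia targets on Disk (0.67), mesenchymal transition on Y (0.174), and the interferon response on Crossbow against the others (-0.163). In the camera test, against other genes, DNA replication stayed lower there on Disk (adjusted p = 0.0024) and Y (0.0073). The authors' scaled values kept 31, ended 17 calls, DNA replication on Y (adjusted p = 0.064) and L (0.054) among them, and turned 4 means, those of tubulins on Disk (0.105), Y (0.241) and Disk against the others (0.00939), and of hypoxia targets on Disk (0.151).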

Other observations

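The tests by shape were secondary and planned, whereas their other scalings and the classes of short RNA were chosen after values were seen. Mitosis, DNA replication, heat shock and ribosomal protein lists passed camera on each of the 5 shapes. Mitosis genes fell in 18 of 25 on Disk and on Crossbow, 16 on H and on Y, and 15 on L, with 0 higher in any shape, and the mean stayed below 0 under every scaling. DNA replication genes had a mean below 0 in every shape (-0.754 on Crossbow to -0.454 on L), but above 0 on Disk (0.0557) and Y (0.149) under median centring, where the camera test against other genes still called them lower (adjusted p = 0.0024 and 0.0073). Lists that passed on only some shapes are otherwise not described here. YAP and TAZ targets passed on Disk (camera adjusted p = 0.0039), Crossbow (0.0036) and H (0.0074), also with an estimated correlation (adjusted p = 0.027, 0.023 and 0.034), but only Crossbow kept its call under median centring (0.0017) and with the authors' scaled values (0.0024). They did not pass on Y or L, but did with normexp and an offset (adjusted p = 0.024 and 0.033).

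The difference itself, in each shape against the others, gave lower YAP and TAZ targets on Disk (mean -0.216; adjusted p = 0.031, but 0.11 with an estimated correlation and a mean of 0.0191 under median centring). It gave higher ones on Y (0.0083, kept at 0.019 under median centring and 0.017 with the authors' scaled values, but 0.066 with an estimated correlation). Oxidative phosphorylation genes were lower on H than on the other shapes, with 5 of 28 lower and 0 higher (camera adjusted p = 0.00098, with an estimated correlation 0.023, under median centring 0.039). On Crossbow 10 of 28 were lower and 1 higher than on the others, but the list passed camera only under median centring (mean -0.759; adjusted p = 9.6e-05) and with the authors' scaled values (-0.415; 1.6e-08). Cholesterol synthesis genes were lower on Disk than on the others in 5 of 18 (0.0098, but adjusted p = 0.087 with an estimated correlation, and a mean of 0.0631 under median centring). Interferon response genes were higher on Crossbow in 5 of 17 (0.0092, but adjusted p = 0.11 with an estimated correlation, and a mean of -0.163 under median centring).

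The other lists past the threshold in these contrasts did not pass with an estimated correlation (adjusted p = 0.066 to 0.19). Fibroblast markers were lower on Y (0.00074; 1 of 5 called lower) under every scaling. Mitosis (0.027) and DNA replication genes (0.022) were higher on L than on the other shapes under every scaling, with 4 of 25 and 2 of 18 called, but without background correction neither passed (adjusted p = 0.065 for both), nor did mitosis with normexp and an offset (0.053). On H, camera called the tubulin, nuclear envelope and autophagy lists higher and the histone list lower (0.024 each), although few members were called: 3 of 13, 2 of 14 and 2 of 17 higher (with 1 autophagy gene lower), and 1 of 7 lower. The means kept their signs under every scaling, but none of these 4 lists passed under median centring (adjusted p = 0.07 to 0.22). On Disk, the histone list was higher (0.044; 3 of 7 called) under every scaling, without a call under median centring (adjusted p = 0.18), and the tubulin list lower (0.044; 4 of 13 called), but its mean was above 0 under median centring (0.225) and with the authors' scaled values (0.00939).

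Of 4 ribosomal RNA probes, 4 rose on patterned arrays: RNA28SN5 by 2.06 and 1.61 log2 on its probes, RNA18SN5 by 1.45 and RNA5S9 by 0.95. Of 9 snRNA probes, 7 rose, among them RNU6-1, the U6 RNA, by 0.94 and RNU1-1 by 0.62, whereas the probes of RNU11, of the minor spliceosome, had 0.081 and 0.064 (adjusted p = 0.55 and 0.64). Of 70 snoRNA probes, 6 rose and 2 fell, with a median of 0.051, and the rises were led by the U3 copies SNORD3C, SNORD3A and SNORD3D (2.39). The Y RNA genes RNY3 (0.22; adjusted p = 0.096) and RNY5 (0.033; adjusted p = 0.81), RMRP of RNase MRP (0.20; adjusted p = 0.099) and RPPH1 of RNase P (0.093; adjusted p = 0.56) did not pass. All 4 ribosomal RNA probes and RNU6-1 and RNU1-1 stayed above 0 under median centring and with the authors' scaled values (RNU1-1 0.0861 with the latter).

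In a principal component analysis of the tested probes, the first component held 34.2% of the variance and set the nonrestricted arrays (-54.9 to -35.8) apart from the patterned arrays (4.79 to 17.1). The second, with 15.5%, set the Crossbow arrays (-28.6 to -25.2) apart from Y and L (9.12 to 16.1). The third, with 10.7%, set nonrestricted replicate 2 (-30.1) apart from the other nonrestricted arrays (15.4 and 17.1).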
